A study of Mus musculus with 27 samples.

How the data were processed

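Total RNA from embryonic mouse hearts at stage E11.5, of a mixed strain background, was labelled with biotin and hybridised to Affymetrix arrays with 1 array per sample, per the labels. The deposited table holds log2 signals of 28815 probe sets on 27 arrays, summarised by the authors with Affymetrix Power Tools and RMA, per the submitters' processing notes, which give no versions. The values ran from 1.64 to 15.144 with array medians between 6.181 and 6.328, and the sorted values differed between arrays by at most log2 0.343. They were used as deposited, without a further transformation or normalization. The correlation between 2 arrays was 0.973 at the lowest and 0.995 at the highest. Arrays carry no counts, so the number of arrays sets the precision, and 8194 probe sets had a mean below log2 5.

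Probe sets were paired with genes through the platform annotation. Of the 28815 probe sets, 21780 had 1 gene symbol, 1605 had several and 5430 were not listed. Probe sets with 1 symbol were kept, and for the 998 genes with several probe sets the probe set with the highest mean over all arrays was taken, which left 19935 genes. Of these, 19853 matched the reference gene table of assembly GRCm38.p6 by gene identifier. The labels name no genome build, so no coordinates are given and that table was used only for names and for which genes neighbour each other.

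Arrays were grouped by the genotype in the labels into 6 groups. Differences were estimated with limma 3.58.1 in R 4.3.3, with a mean per group, all 27 arrays in a shared fit and an empirical Bayes variance prior without trend (21 residual and 6.71 prior degrees of freedom). The 9 comparisons were each of the single and compound losses against wild type, each compound loss against the single loss of its transcription factor, and the interaction of Brg1 with each factor, which is the effect of Brg1 loss in hearts with the factor loss minus its effect in hearts without it. Tests were two-sided, p was adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. All adjusted p of single genes are limma adjusted p, and they treat the arrays as independent embryos, which the labels do not state.

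Gene lists were written for the tissue before the data were examined, as were the comparisons, the rule for named genes and the alternatives except those said to be added later. There were 25 lists, of which 23 were tested as sets, and the lists of targeted and sex-linked genes were used by gene. Sets were tested with limma's camera at a preset correlation of 0.01, with p adjusted over the lists within a comparison, and again with an estimated correlation and with fry. Counts of members are given over all genes and adjusted over the list alone. In the list tests, calls that held with an estimated correlation numbered 0 of 94, and the adjusted p of each named list is given beside it.

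Genes were named by this rule. Smarca4, Tbx5 and Nkx2-5 are given in every comparison. In each comparison the 10 called genes with the largest rise and the 10 with the largest fall could be named, or, where fewer than 5 genes passed, the 5 with the smallest p as values without a call. From each list up to 4 called members with the smallest p could be named, or, where none passed, the 2 with the smallest p as values without a call. Clone, predicted, accession-like and olfactory or vomeronasal receptor names were counted but not named among the largest changes, and some genes that the rule allows were left out.

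Alternatives were a further quantile normalization, array medians equalised, removal of the third of genes with the lowest means, a trended and robust variance prior, the arrays of the compared groups alone, all probe sets, the mean of a gene's probe sets, array weights, the replicate number as a block, the mean of the erythroid list, the mean of the Y-linked genes or the first residual principal component as a covariate, and each array left out in turn. Female-like and male-like arrays, by the sex-linked genes, numbered 5 and 1 in wild type, 3 and 3 in Brg1+/-, 3 and 2 in Tbx5+/-, 3 and 1 in Nkx2-5+/-, 2 and 1 in Tbx5+/-;Brg1+/- and 1 and 2 in Nkx2-5+/-;Brg1+/-. Comparisons against the same wild-type arrays were set beside 100 simulated unchanged groups and 20 splits of the wild-type arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

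The fit was tested on simulated data with independent noise, in which 67 genes were changed by log2 0.5, 67 by log2 1 and 66 by log2 2 among the 19935. In the comparison of Brg1+/- with wild type, 61.2%, 97.0% and 100% of these were called. For Tbx5+/- the shares were 55.2%, 98.5% and 100%, and for Nkx2-5+/- 44.8%, 97.0% and 100%. For Tbx5+/-;Brg1+/- they were 37.3%, 89.6% and 100% against wild type and 46.3%, 95.5% and 100% against Tbx5+/-. For Nkx2-5+/-;Brg1+/- they were 47.8%, 95.5% and 98.5% against wild type and 26.9%, 94.0% and 100% against Nkx2-5+/-. For the interactions of Brg1 they were 10.4%, 79.1% and 98.5% with Tbx5 and 17.9%, 88.1% and 98.5% with Nkx2-5. Between 4 and 14 unchanged genes were called per comparison, and 0 of the 23 unchanged lists. Independent noise holds no correlation between genes and no shift that many genes share, such as blood content. These numbers of false calls therefore do not carry over to the real arrays, and they do not test the preset correlation of camera.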

Results

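RNA from mouse embryo hearts at stage E11.5 was profiled on 27 arrays that fall into 6 genotype groups. The groups were wild type (n = 6) and hearts labelled as carrying a deletion of 1 copy of Brg1 (n = 6), Tbx5 (n = 5) or Nkx2-5 (n = 4), of both Tbx5 and Brg1 (n = 3), or of both Nkx2-5 and Brg1 (n = 3). Brg1, encoded by Smarca4, is the ATPase of the BAF chromatin remodelling complex, and Tbx5 and Nkx2-5 are transcription factors of the developing heart. The design asks what each single loss does to heart gene expression, and whether the loss of 1 copy of Brg1 alters the effect of losing 1 copy of either transcription factor. Values are RMA log2 signals of 19935 genes, and the array medians lay between 6.18 and 6.33. Groups are named throughout by the genotype in the labels, and the number of arrays limits the precision of every value.

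Smarca4 (probe set 10583697) was 10.07 ± 0.07 (SD, n = 6) in wild-type hearts and 9.32 ± 0.13 (SD, n = 6) in hearts labelled Brg1+/-, and every Brg1+/- array lay below every wild-type array. It was 9.45 ± 0.17 (SD, n = 3) in hearts labelled Nkx2-5+/-;Brg1+/- and 9.72 ± 0.26 (SD, n = 3) in those labelled Tbx5+/-;Brg1+/-. Hearts labelled Tbx5+/- and Nkx2-5+/- had Smarca4 values of 10.07 ± 0.11 (SD, n = 5) and 9.90 ± 0.23 (SD, n = 4). A pair of arrays went against their labels. Nkx2-5+/- replicate 3 had a Smarca4 signal of 9.57, inside the range of 9.16 to 9.64 of the 11 other arrays with a Brg1 deletion in the label. Tbx5+/-;Brg1+/- replicate 3 had 10.01, inside the range of 9.89 to 10.23 of the 14 other arrays without one. Directions drawn from these groups therefore hold for arrays as labelled. Nkx2-5 (probe set 10449292) was 8.74 ± 0.44 (SD, n = 4) in arrays labelled Nkx2-5+/-, against 9.59 ± 0.34 (SD, n = 6) in wild type, with replicate 3 at 9.40. The other 3 arrays lay between 8.48 and 8.63. The Nkx2-5 signal of replicate 3 thus also went against its label, above the 8.48 to 9.24 of the 6 other arrays with an Nkx2-5 deletion in the label and inside the 8.99 to 10.01 of 19 arrays without one. In arrays labelled Nkx2-5+/-;Brg1+/- it was 9.04 ± 0.19 (SD, n = 3). In those labelled Brg1+/-, Tbx5+/- and Tbx5+/-;Brg1+/- it was 9.39 ± 0.26 (SD, n = 6), 9.90 ± 0.13 (SD, n = 5) and 9.83 ± 0.16 (SD, n = 3). Tbx5 (probe set 10525030) was 8.80 ± 0.17 (SD, n = 5) in arrays labelled Tbx5+/- and 8.61 ± 0.10 (SD, n = 3) in those labelled Tbx5+/-;Brg1+/-, against 8.57 ± 0.20 (SD, n = 6) in wild type. The labels do not say which part of Tbx5 the deletion removes, so this probe set checks nothing about the Tbx5 labels. Tbx5 was 8.12 ± 0.21 (SD, n = 6) in arrays labelled Brg1+/-, 8.07 ± 0.32 (SD, n = 4) in those labelled Nkx2-5+/- and 8.51 ± 0.10 (SD, n = 3) in those labelled Nkx2-5+/-;Brg1+/-.

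**Figure D1:**
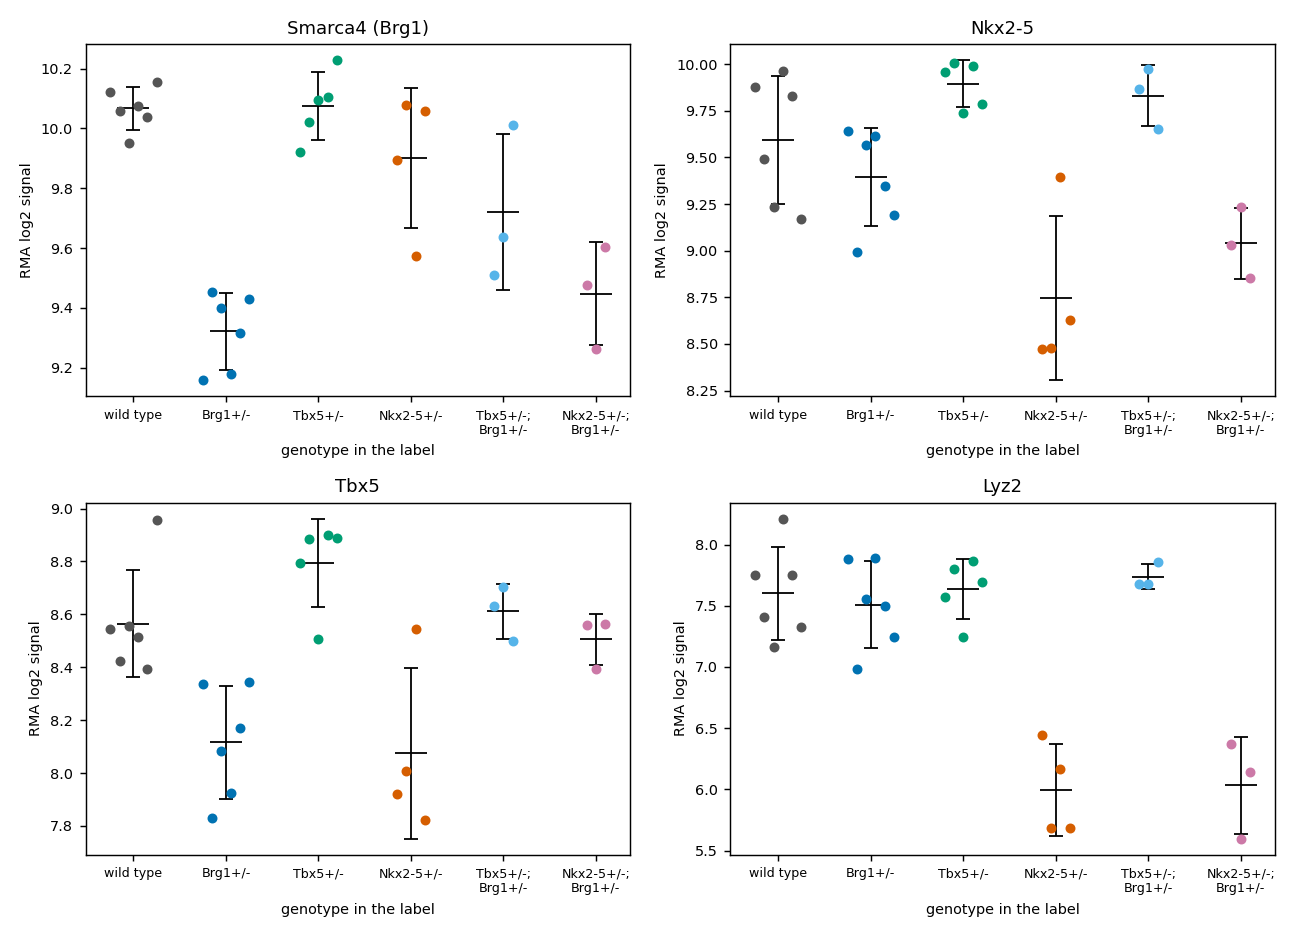
RMA log2 signal (vertical axis) of Smarca4, Nkx2-5, Tbx5 and Lyz2 in each of the 27 arrays, grouped by the genotype in the label (horizontal axis); points are arrays, and the bar and whiskers are the mean ± SD of a group. Smarca4 of Nkx2-5+/- replicate 3 lies at 9.57 and that of Tbx5+/-;Brg1+/- replicate 3 at 10.01, each against its label, and the vertical axes do not start at 0.

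Hearts labelled Brg1+/- differed from wild-type hearts in 2 genes, both lower. Smarca4 fell by 0.74 on the log2 scale (SE 0.09, adjusted p = 3.1e-04, n = 6 and 6), which is 1.68-fold lower. Igfbp2, a binding protein of insulin-like growth factors, fell by 0.65 (SE 0.11, adjusted p = 0.0362). Among genes that did not pass, the muscle gene Tnni2 had a log2 fold change of -0.77 (adjusted p = 0.254), the GTPase gene Gimap9 -0.57 (adjusted p = 0.254) and Ofcc1 0.40 (adjusted p = 0.254). The other targeted genes did not pass either, with -0.45 for Tbx5 (adjusted p = 0.328) and -0.20 for Nkx2-5 (adjusted p = 0.671). Shox2, a transcription factor of the sinus node, stood at -0.64 (adjusted p = 0.379), and the atrial transcription factors Nr2f1 and Nr2f2 at -0.60 (adjusted p = 0.303) and -0.43 (adjusted p = 0.379). limma gave 1935 genes at an unadjusted p under 0.05, where chance gives 996.75 of the 19935. The Igfbp2 call ended, leaving 1 gene, without Brg1+/- replicate 2, 3, 5 or 6 or wild-type replicate 1, 4 or 5, and it ended also without wild-type replicate 2, where 3 genes passed. It ended as well with the erythroid list mean or the Y-linked mean as a covariate, after a further quantile normalization and with the arrays of these groups alone, each of which left 1 gene. The log2 fold change of Igfbp2 lay between -0.73 and -0.60 in all 25 alternatives.

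In hearts labelled Brg1+/-, the erythroid list, genes of red blood cells, had a median log2 fold change of 0.88 (camera adjusted p = 1.2e-12; adjusted p = 0.314 with an estimated correlation), and 0 of its 15 members passed over all genes while 10 rose adjusted over the list alone. Its members Hemgn and Gata1, nuclear regulators of red cell formation, had log2 fold changes of 1.66 and 1.23 (adjusted p = 0.409 for each). Beside this, the sarcomere list, the contractile apparatus of heart muscle, had a median of -0.18 with 31 of 32 members below 0 (camera adjusted p = 1.7e-04; adjusted p = 0.371 with an estimated correlation). With the erythroid list mean as a covariate the sarcomere median was 0.026 (camera adjusted p = 0.898). The leukocyte and platelet list had a median of -0.19 (camera adjusted p = 2.5e-04; adjusted p = 0.314 with an estimated correlation), with 0 members past the test over all genes and 7 lower adjusted over the list alone. Its macrophage genes Mrc1 and Adgre1 stood at -0.71 (adjusted p = 0.318) and -0.45 (adjusted p = 0.379). The cell cycle list had a median of 0.12 (camera adjusted p = 6.0e-05; adjusted p = 0.314 with an estimated correlation). In all, camera called 18 of the 23 lists in this comparison, and none of them held with an estimated correlation, under which the adjusted p of the 18 lay between 0.314 and 0.454. With the erythroid list mean as a covariate 5 of the 18 held.

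Hearts labelled Tbx5+/- showed 0 genes past the test by limma against wild type, with 788 genes at an unadjusted p under 0.05 and 0 under every other setting run. Among the values with the smallest p, Gja5, the gap junction protein of the atria and the fast conduction system, had a log2 fold change of -0.63 (SE 0.17), the potassium channel gene Kcna5 -0.47, the calcium sensor gene Vsnl1 -0.65, the methyltransferase gene Eef2kmt 0.46 and Slc35d3 -0.46. Their adjusted p was 1.0 for each after rounding. The transcription factor genes Shox2, Tbx3 and Irx4 stood at -0.63, -0.38 and 0.52, the growth factor gene Bmp2 at -0.50 and the Notch ligand gene Jag1 at -0.40. Of the targeted genes, Tbx5 stood at 0.23, Nkx2-5 at 0.30 and Smarca4 at 0.01. The Smarca4 value was below 0 without Tbx5+/- replicate 4 or 5 or wild-type replicate 3, with -0.031 as the lowest.

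Among the lists, genes of muscle and of its energy supply stood above 0 in hearts labelled Tbx5+/-, and genes of the non-muscle tissues of the heart stood below. The mitochondrial and fatty acid list had a median log2 fold change of 0.14 (camera adjusted p = 0.0012; adjusted p = 0.727 with an estimated correlation) and the sarcomere list 0.12 (camera adjusted p = 0.0015; adjusted p = 0.813 with an estimated correlation). The atrioventricular canal and outflow tract list had a median of -0.19 (camera adjusted p = 0.0014), the cushion mesenchyme list -0.17 (camera adjusted p = 0.0014) and the Bmp and Tgf-beta list -0.14 (camera adjusted p = 0.0027), each with an adjusted p = 0.727 with an estimated correlation. The endothelium list stood at -0.14 (camera adjusted p = 0.0014) and the epicardium list at -0.10 (camera adjusted p = 0.0351), each with an adjusted p = 0.741 with an estimated correlation. The erythroid list stood at 0.03. Over all genes 0 members of these 7 lists passed, and adjusted over the list alone 1 member fell in the atrioventricular canal list and in the chamber myocardium and conduction lists. The cushion call ended without Tbx5+/- replicate 1 (camera adjusted p = 0.0536), and the endothelium call without Tbx5+/- replicate 3 or wild-type replicate 6 (0.0603 to 0.0851). The epicardium call ended without Tbx5+/- replicate 1, 2, 4 or 5 or wild-type replicate 1, 3 or 6 (0.0813 to 0.209).

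In arrays labelled Tbx5+/-;Brg1+/-, Gja5 had a log2 fold change of -1.10 against wild type (SE 0.19, adjusted p = 0.102), the vesicular transporter gene Slc17a7 -0.70 (adjusted p = 0.145), Vsnl1 -0.86 (adjusted p = 0.606), Kcna5 -0.77 (adjusted p = 0.649) and the vesicle coat gene Ap3b2 -0.78 (adjusted p = 0.649). Bmp2 and the conduction system factor Tbx3 stood at -0.64 and -0.37 (adjusted p = 0.979 for each). Smarca4 stood at -0.35 (adjusted p = 0.979), with replicate 3 at the wild-type level, Tbx5 at 0.05 and Nkx2-5 at 0.24. limma called 0 genes, with 873 at an unadjusted p under 0.05. Other settings gave 1 gene with the arrays of these groups alone, 1 with all probe sets, 1 with the first residual principal component as a covariate and 6 with array weights. The adjusted p of Gja5 was 0.0046 with the arrays of these groups alone, 0.0057 with array weights and 9.4e-04 with the principal component.

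In the lists, the liver list had a median of -0.44 in the Tbx5+/-;Brg1+/- arrays against wild type (camera adjusted p = 0.0018), the cushion mesenchyme list -0.20 (camera adjusted p = 0.0077) and the Bmp and Tgf-beta list -0.15 (camera adjusted p = 0.0084), each with an adjusted p = 0.632 with an estimated correlation. The conduction list was called (camera adjusted p = 0.0210; adjusted p = 0.632 with an estimated correlation) at a median of -0.02 and a mean of -0.14, with 0 members past the test over all genes and 3 lower adjusted over the list alone. The erythroid list stood at 0.22. Without wild-type replicate 3, whose liver list mean was 7.58 against 5.39 to 6.07 in the other wild-type arrays, the liver median was -0.13 (camera adjusted p = 0.166). The cushion and Bmp calls ended without Tbx5+/-;Brg1+/- replicate 3 or wild-type replicate 6 (camera adjusted p = 0.0605 to 0.633), and the conduction call without these or wild-type replicate 5 (0.0535 to 0.142). Of the 8 lists called, 2 held with the erythroid list mean as a covariate, and 1 without the pair of arrays whose Smarca4 went against the label, a setting added after the data were seen.

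Between arrays labelled Tbx5+/-;Brg1+/- and those labelled Tbx5+/- alone, Tchhl1 had a log2 fold change of 0.56 and Cct8l1 0.65 (adjusted p = 0.639 for each), the smooth muscle myosin gene Myh11 stood at 0.46, Gja5 at -0.47, Kcna5 at -0.31 and Smarca4 at -0.36 (adjusted p = 1.0 for each after rounding). Tbx5 stood at -0.18 and Nkx2-5 at -0.06, and the Nkx2-5 value was 0.025 without Tbx5+/-;Brg1+/- replicate 3. limma called 0 genes, with 494 at an unadjusted p under 0.05, and 2 with array weights. The mitochondrial list (median -0.10), the liver list (-0.39) and the skeletal and pharyngeal muscle list (0.23) each had a camera adjusted p = 0.0196, and each an adjusted p = 0.991 with an estimated correlation. The mitochondrial call ended without Tbx5+/- replicate 4 or Tbx5+/-;Brg1+/- replicate 3 (0.0518 to 0.102), the liver call without Tbx5+/- replicate 1, 4 or 5 or Tbx5+/-;Brg1+/- replicate 2 (0.0597 to 0.221), and the skeletal muscle call without Tbx5+/- replicate 5 or Tbx5+/-;Brg1+/- replicate 1 (0.0548 to 0.356). The erythroid list stood at 0.17 there.

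The Tbx5 by Brg1 interaction asks whether the joint effect departs from the sum of the single effects on the log2 scale. For Smarca4 the interaction was 0.39, for Tbx5 0.27 and for Nkx2-5 0.14. The erythroid list had a median interaction of -0.71 (camera adjusted p = 1.8e-06), the cell cycle list -0.13 (camera adjusted p = 0.0013) and the atrioventricular canal list 0.25 (camera adjusted p = 0.0386), each with an adjusted p = 0.783 with an estimated correlation. None of the 3 held with the erythroid list mean as a covariate. The cell cycle call ended without Brg1+/- replicate 2 (camera adjusted p = 0.0825), and the atrioventricular canal call without Brg1+/- replicate 1 or 4, Tbx5+/- replicate 1 or 2, Tbx5+/-;Brg1+/- replicate 1 or 2, or wild-type replicate 3 (0.0656 to 0.0994). limma called 0 genes, with 606 at an unadjusted p under 0.05, 2 with array weights and 1 with the erythroid list mean as a covariate. In this comparison the simulated data had 10.4% of changes of log2 0.5 and 79.1% of changes of log2 1 called.

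Hearts labelled Nkx2-5+/- had 543 genes higher and 1029 lower than wild-type hearts. Nkx2-5 itself fell by 0.85 (SE 0.17, adjusted p = 0.0070), which is 1.80-fold lower, and Tbx5 fell by 0.49 (SE 0.13, adjusted p = 0.0225). The largest falls included Lyz2, a lysozyme, at -1.61 (SE 0.20, adjusted p = 1.5e-04), and its paralog Lyz1 at -1.21 (adjusted p = 6.6e-04). They also included the mitochondrial enzyme gene Aldh1b1 at -1.19, the respiratory chain gene Cox8b at -1.18, the calcium store gene Casq2 at -1.06, the lipoprotein lipase gene Lpl at -1.06 and the heart muscle gene Lrrc10 at -1.06. The largest rises included genes of red blood cells: Hemgn rose by 2.03, the red cell pyruvate kinase gene Pklr by 1.80, Gata1 by 1.74, the erythropoietin receptor gene Epor by 1.62 and the blood lineage factor Ikzf1 by 1.53. Smarca4 stood at -0.17 (adjusted p = 0.384). Igfbp2 fell by 0.77 (adjusted p = 0.0023) and was named after its values were seen. Of the 1572 genes, 549 changed at least 1.5-fold and 93 at least 2-fold. The count was 895, 66, 4368 and 224 without Nkx2-5+/- replicates 1, 2, 3 and 4, and 754, 593 and 841 without wild-type replicates 1, 4 and 5. It was 4346 without the pair of arrays whose Smarca4 went against the label, 3744 with array weights, 2992 with the first residual principal component as a covariate, and 4 with the arrays of these groups alone. It was 4 with the erythroid list mean as a covariate, where Lyz2 and Lyz1 were still called and Nkx2-5 stood at -0.54 (adjusted p = 0.267).

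Heart muscle genes were lower across several lists in arrays labelled Nkx2-5+/-, while the erythroid list was higher with a median log2 fold change of 1.26. Replicate 3 did not share the lower level, with a sarcomere mean of 10.89 (others 9.96 to 10.08, wild type 10.47 to 10.95), a chamber myocardium mean of 10.36 (others 9.46 to 9.76) and a mitochondrial mean of 9.84 (others 9.24 to 9.44). Of 32 sarcomere genes 17 fell and 0 rose, and 23 fell and 1 rose adjusted over the list alone (median -0.47, camera adjusted p = 4.4e-12; adjusted p = 0.250 with an estimated correlation). Among them, the Z-disc protein gene Myoz2 fell by 0.95, the intermediate filament gene Des by 0.85, the actin nucleator gene Lmod2 by 0.81 and Smpx by 0.78. In the mitochondrial and fatty acid list 11 of 19 fell, 15 adjusted over the list alone (median -0.48, camera adjusted p = 5.4e-10; adjusted p = 0.250 with an estimated correlation), including the respiratory chain genes Cox6a2 (-0.83) and Cox7a1 (-0.62), the coactivator gene Ppargc1a (-0.71) and the fatty acid oxidation gene Acadl (-0.68). In the chamber myocardium list 8 of 17 fell, 10 adjusted over the list alone (median -0.42, camera adjusted p = 7.2e-08; adjusted p = 0.250 with an estimated correlation), including the ventricular light chain gene Myl2 (-0.42) and Nr2f1 (-0.59). In the calcium handling list 3 of 14 fell, 7 adjusted over the list alone (median -0.36, camera adjusted p = 8.8e-06; adjusted p = 0.250 with an estimated correlation), among them Pln, which restrains the calcium pump (-0.86), and S100a1 (-0.60). Of 24 conduction genes 3 fell, 5 adjusted over the list alone (median -0.18, camera adjusted p = 0.0092; adjusted p = 0.258 with an estimated correlation): the potassium channel genes Kcne1 (-0.82), Kcnj2 (-0.71) and Kcnq1 (-0.36). The glycolysis and hypoxia list had 7 of 22 genes lower, 12 adjusted over the list alone (median -0.40, camera adjusted p = 6.6e-06; adjusted p = 0.258 with an estimated correlation), including the vasodilator peptide gene Adm (-0.71) and the glycolytic enzyme gene Pgam1 (-0.60).

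Beside the same erythroid median of 1.26 in arrays labelled Nkx2-5+/-, of 40 cardiac transcription factors 9 fell and 0 rose, and 13 fell and 2 rose adjusted over the list alone (median -0.28, camera adjusted p = 2.3e-05; adjusted p = 0.258 with an estimated correlation), with Hopx at -0.89, the muscle methyltransferase Smyd1 at -0.76, Hey2 at -0.64 and Gata6 at -0.52. Of 13 epicardial genes 6 fell, 7 adjusted over the list alone (median -0.39, camera adjusted p = 2.1e-05; adjusted p = 0.250 with an estimated correlation), including the surface protein gene Msln (-0.70), the guidance cue gene Sema3d (-0.57) and the transcription factor gene Tcf21 (-0.45). In the Bmp and Tgf-beta list 5 of 20 fell, 6 adjusted over the list alone (median -0.20, camera adjusted p = 5.0e-04; adjusted p = 0.293 with an estimated correlation). In the atrioventricular canal and outflow tract list 3 of 14 fell, 3 adjusted over the list alone (median -0.15, camera adjusted p = 0.0358; adjusted p = 0.391 with an estimated correlation), with Bmp4 at -0.61 and the outflow tract guidance cue Sema3c at -0.78. In the Notch and neuregulin list 3 of 15 fell, 3 adjusted over the list alone, among them the receptor gene Erbb2 (-0.51) (median -0.09, camera adjusted p = 0.0483; adjusted p = 0.470 with an estimated correlation). With the erythroid list mean as a covariate the median of this list was 0.030 (camera adjusted p = 0.857). Of 18 cushion genes 1 fell, the matrix gene Lum at -1.04 (adjusted p = 0.0228; list median -0.26, camera adjusted p = 0.0044; adjusted p = 0.356 with an estimated correlation). The endothelium list had 0 of 20 members past the limma test, with a median of -0.25 (camera adjusted p = 0.0326; adjusted p = 0.548 with an estimated correlation). Its median was -0.00894 with that covariate, where the test direction turned (camera adjusted p = 0.838). Of the 18 lists called in this comparison, 9 held with that covariate. The atrioventricular canal call ended without Nkx2-5+/- replicate 1 or 2 or wild-type replicate 3 or 6 (0.0501 to 0.288), and the Notch call without these Nkx2-5+/- arrays or wild-type replicate 3, 5 or 6 (0.0516 to 0.430). The cushion call ended without Nkx2-5+/- replicate 2 (0.143), and the endothelium call without Nkx2-5+/- replicate 2, 3 or 4 or wild-type replicate 3 or 6 (0.0582 to 0.381).

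In the erythroid list of arrays labelled Nkx2-5+/-, 4 of 15 genes rose over all genes and 15 adjusted over the list alone (camera adjusted p = 5.4e-10; adjusted p = 0.250 with an estimated correlation), including the spectrin gene Sptb (1.38) and the embryonic globin gene Hbb-bh1 (0.92). Of 27 cell cycle genes 5 rose, 6 adjusted over the list alone (median 0.20, camera adjusted p = 8.8e-06; adjusted p = 0.306 with an estimated correlation), with the proliferation marker Mki67 at 1.24, the spindle motor gene Kif11 at 0.61 and the mitotic kinase gene Aurka at 0.43. In the immediate early and heat shock list 2 of 19 rose, the feedback phosphatase gene Dusp1 (0.75) and the antiproliferative gene Btg2 (0.73), at a list median of 0.07 (camera adjusted p = 0.0291; adjusted p = 0.250 with an estimated correlation). Of 16 leukocyte and platelet genes 3 fell, 5 adjusted over the list alone (median -0.24, camera adjusted p = 0.0017; adjusted p = 0.355 with an estimated correlation): Lyz2 and the macrophage receptor genes Mrc1 (-0.70) and Csf1r (-0.58). Among 27 BAF subunits, Pbrm1 rose by 0.42, Smarcd3, the heart-enriched subunit, fell by 0.52, and Smarca2, the other ATPase, fell by 0.46, while the list was not called (camera adjusted p = 0.357). The leukocyte call ended without Nkx2-5+/- replicate 3 (camera adjusted p = 0.530), and the immediate early call without it or wild-type replicate 6 (0.0607 to 0.221). The mean of the erythroid list was between 11.77 and 11.91 in Nkx2-5+/- replicates 1, 2 and 4 and 9.96 in replicate 3, against 9.53 to 11.02 in wild type.

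**Figure D2:**
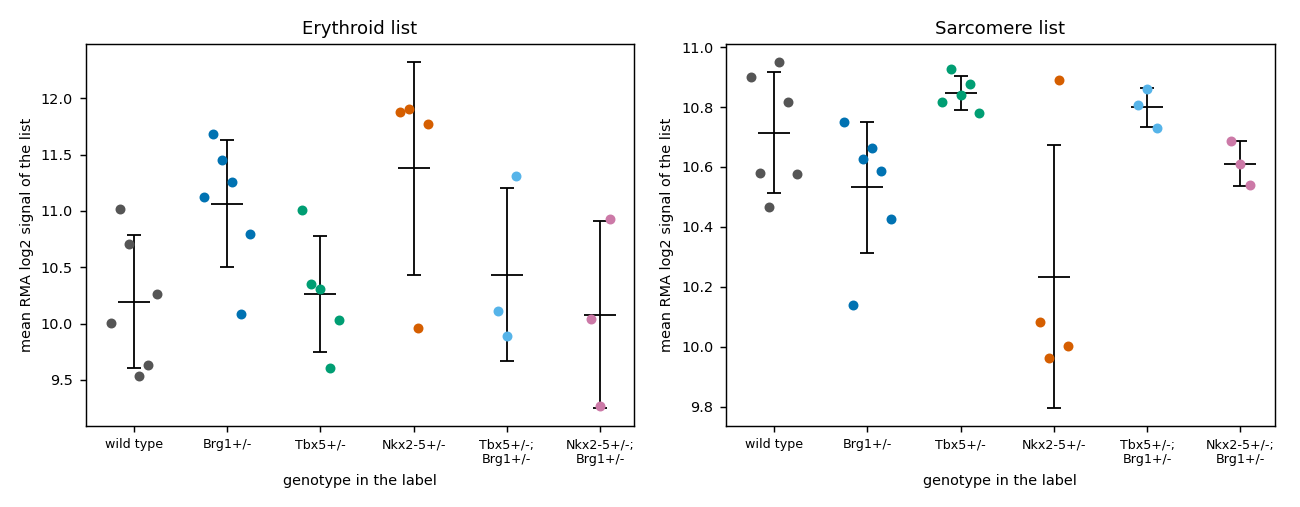
Mean RMA log2 signal (vertical axis) of the 15 measured erythroid genes (left) and of the 32 measured sarcomere genes (right) in each array, by the genotype in the label (horizontal axis); points are arrays, and the bar and whiskers are the mean ± SD of a group. Nkx2-5+/- replicate 3 lies at an erythroid mean of 9.96, below the 11.77 to 11.91 of the other 3 arrays of its group, and the vertical axes do not start at 0.

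**Figure D3:**
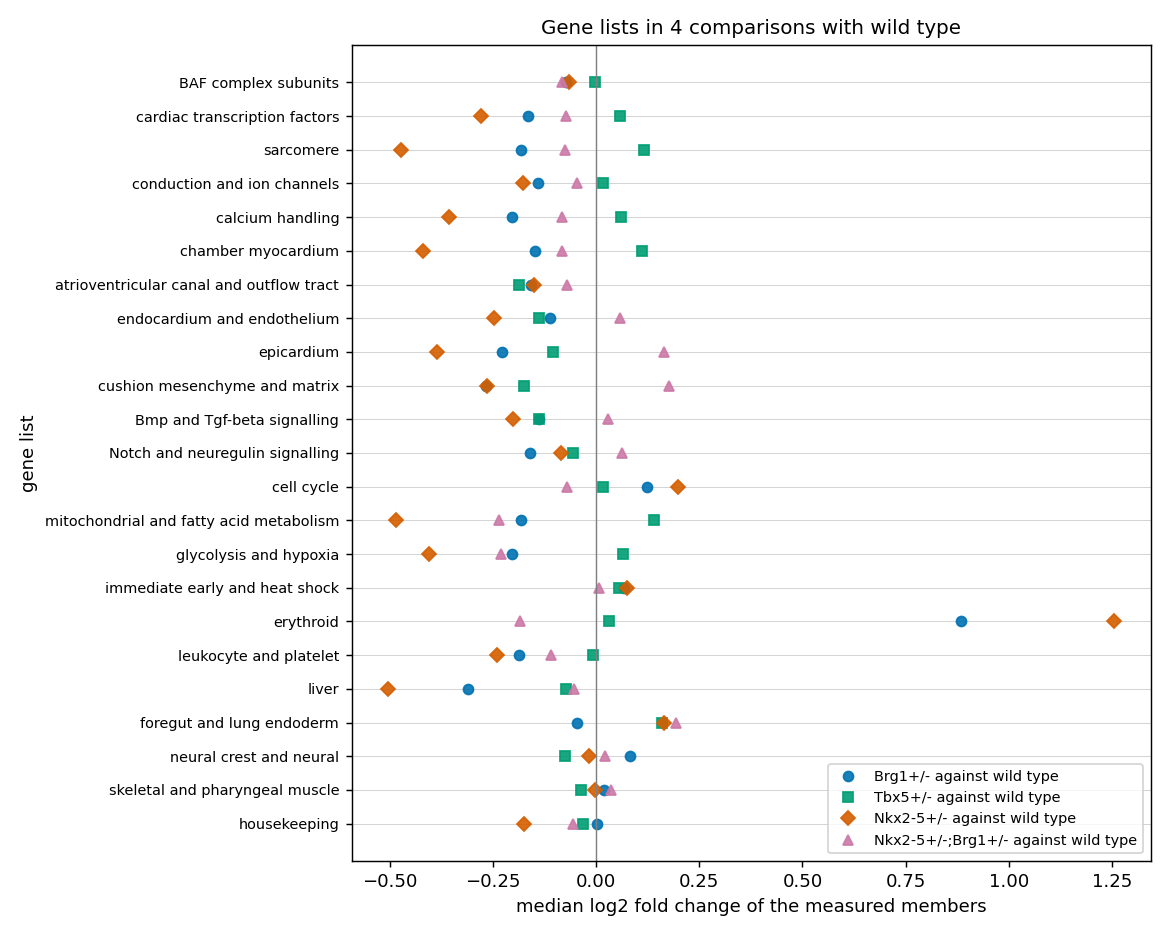
Median log2 fold change against wild type (horizontal axis) of the measured members of the 23 tested gene lists (vertical axis) in arrays labelled Brg1+/- (circles), Tbx5+/- (squares), Nkx2-5+/- (diamonds) and Nkx2-5+/-;Brg1+/- (triangles). The erythroid list stands at 1.26 and 0.88 in the Nkx2-5+/- and Brg1+/- arrays and at 0.03 and -0.18 in the Tbx5+/- and Nkx2-5+/-;Brg1+/- arrays.

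Hearts labelled Nkx2-5+/-;Brg1+/- differed from wild type in 7 genes, 5 lower and 2 higher. The lysozyme genes Lyz2 and Lyz1 fell by 1.57 (SE 0.22, adjusted p = 0.0013) and 1.06 (adjusted p = 0.0278), and Lyz2 was 2.97-fold lower. Igfbpl1, a relative of the insulin-like growth factor binding proteins, fell by 1.06 (adjusted p = 0.0278) and Igfbp2 by 0.78 (adjusted p = 0.0278). Smarca4 fell by 0.62 (SE 0.12, adjusted p = 0.0391). Orm2, an acute phase protein gene, rose by 0.55 (adjusted p = 0.0391) and Ccdc74a by 0.49 (adjusted p = 0.0496). Orm2 had means of 4.62 with both deletions and 4.07 in wild type, both below log2 5. It was called in 8 of 21 alternatives, and Ccdc74a in 7 of 22. Nkx2-5 did not pass, at -0.55 (adjusted p = 0.521), and Tbx5 stood at -0.06, or 0.019 without wild-type replicate 6. The natriuretic peptide gene Nppb stood at 0.57 (adjusted p = 0.538), the epicardial factor gene Tbx18 at 0.47 (adjusted p = 0.550), Des at -0.45 (adjusted p = 0.655) and Smyd1 at -0.44 (adjusted p = 0.644). The count of genes was 1 and 0 without Nkx2-5+/-;Brg1+/- replicates 1 and 2, 1 without wild-type replicate 1, 2, 4 or 5, and 4 without wild-type replicate 3. Without Nkx2-5+/-;Brg1+/- replicate 3 it was 8, of which 6 were higher and 2 lower, and 4 were among the 7. It was 0 with the arrays of these groups alone, 1 with the Y-linked mean as a covariate or with all probe sets, 3 after a further quantile normalization, 14 with the first residual principal component as a covariate, 11 without the pair of arrays whose Smarca4 went against the label and 1156 with array weights.

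In the lists of that comparison, the mitochondrial list had a median of -0.23 (camera adjusted p = 6.9e-05) and the glycolysis list -0.23 with 22 of 22 members below 0 (camera adjusted p = 2.2e-04), each with an adjusted p = 0.856 with an estimated correlation. The epicardium list stood at 0.16 (camera adjusted p = 0.0023; adjusted p = 0.856 with an estimated correlation), with 0 members past the limma test over all genes and 3 higher adjusted over the list alone. The foregut list stood at 0.19 (camera adjusted p = 0.0216; adjusted p = 0.856 with an estimated correlation), the cushion mesenchyme list at 0.18 and the leukocyte list at -0.11 (camera adjusted p = 0.0352 for each; adjusted p = 0.901 with an estimated correlation). The sarcomere list stood at -0.07 (camera adjusted p = 0.147) and the erythroid list at -0.18. The foregut call ended without Nkx2-5+/-;Brg1+/- replicate 1 or wild-type replicate 4 or 6 (0.0525 to 0.182), and the cushion call without Nkx2-5+/-;Brg1+/- replicate 1 or 3 or wild-type replicate 2, 4 or 5 (0.0697 to 0.182). The leukocyte call ended without Nkx2-5+/-;Brg1+/- replicate 2 or wild-type replicate 4, 5 or 6 (0.0690 to 0.643). Of the 6 lists called, 4 held with the erythroid list mean as a covariate.

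Against arrays labelled Nkx2-5+/- alone, those labelled Nkx2-5+/-;Brg1+/- had 8 genes past the test, 7 higher and 1 lower. Apela, a peptide hormone of early heart development, rose by 1.001 (SE 0.15, adjusted p = 0.0071), which is 2.002-fold. The calcium-binding protein gene S100a6 rose by 0.99 (adjusted p = 0.0201), the collagen-binding matrix gene Fmod by 0.94 (adjusted p = 0.0201), Cst9 by 0.90 and the matrix gene Aebp1 by 0.78 (adjusted p = 0.0311 for each), the tetraspanin gene Cd82 by 0.71 (adjusted p = 0.0470) and the cadherin gene Cdh3 by 0.63 (adjusted p = 0.0252). Cst9 had means of 4.70 with both deletions and 3.80 in Nkx2-5+/- arrays, both below log2 5, and was called in 12 of 19 alternatives. The ubiquitin ligase gene Arel1 fell by 0.83 (adjusted p = 0.0491). Of the targeted genes, Smarca4 stood at -0.45 (adjusted p = 0.0816), Tbx5 at 0.43 (adjusted p = 0.144) and Nkx2-5 at 0.30 (adjusted p = 0.532). The count was 33, 2, 2308 and 4 without Nkx2-5+/- replicates 1, 2, 3 and 4, and 2, 0 and 357 without Nkx2-5+/-;Brg1+/- replicates 1, 2 and 3. Lower genes outnumbered higher ones without Nkx2-5+/-;Brg1+/- replicate 3 (69 higher, 288 lower), with the principal component (533 and 673) and without the third of genes with the lowest means (66 and 74). The count was 0 with the arrays of these groups alone and 1 with the erythroid list mean as a covariate, where Apela was called (1.04, adjusted p = 0.0349). Other counts were 1 with array medians equalised, 3 with the Y-linked mean as a covariate and 88 with a trended robust variance prior. They were 136 after a further quantile normalization, 140 without the third of genes with the lowest means, 1206 with the principal component, 2363 without the pair of arrays whose Smarca4 went against the label and 3680 with array weights.

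In the lists of this comparison, 13 of 13 epicardial genes stood above 0 (median 0.62, camera adjusted p = 6.8e-11; adjusted p = 0.104 with an estimated correlation), 0 past the limma test over all genes and 10 higher adjusted over the list alone. The erythroid list stood at -1.46 (camera adjusted p = 6.8e-11; adjusted p = 0.364 with an estimated correlation), with 13 of 15 lower adjusted over the list alone. Beside it, the sarcomere list stood at 0.40 (camera adjusted p = 9.8e-09; adjusted p = 0.376 with an estimated correlation), with 11 higher and 1 lower adjusted over the list alone. The chamber myocardium list stood at 0.40 (camera adjusted p = 6.2e-07) and the cushion mesenchyme list at 0.45 (camera adjusted p = 3.4e-06), each with 3 higher adjusted over the list alone and an adjusted p = 0.364 with an estimated correlation. The cell cycle list stood at -0.29 (camera adjusted p = 7.5e-08; adjusted p = 0.364 with an estimated correlation), with 7 lower adjusted over the list alone. In all 13 lists were called, of which 6 held with the erythroid list mean as a covariate.

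The Nkx2-5 by Brg1 interaction asks whether the joint loss departs from the sum of the single losses, and 987 genes passed, 445 with a positive and 542 with a negative term. With array medians equalised 284 were positive and 517 negative, and without the third of genes with the lowest means 685 and 702. Positive terms outnumbered negative ones with array weights (2801 and 1434), with the principal component (1360 and 928), without the pair of arrays (2155 and 1103) and with the arrays of these groups alone (17 and 8). They did so also without Nkx2-5+/- replicate 1 (347 and 278), 2 (12 and 2) or 3 (2113 and 1111), Nkx2-5+/-;Brg1+/- replicate 1 (5 and 1) or 2 (8 and 0), or Brg1+/- replicate 3 (333 and 331). Of the 987 genes, 871 had a term of at least 1.5-fold and 318 of at least 2-fold. Genes of heart muscle, epicardium and matrix were among the positive terms and genes of red blood cells among the negative ones. Tbx5 had a positive interaction of 0.88 (SE 0.19, adjusted p = 0.0189), with 8.07 in Nkx2-5+/- and 8.12 in Brg1+/- arrays against 8.51 with both deletions and 8.57 in wild type. The largest positive terms included the matrix genes Lum (1.42), Fbln2 (1.15) and Spon2 (1.23), the sinus node factor Shox2 (1.31), the Z-disc gene Myoz2 (1.23) and Apela (1.12, adjusted p = 0.0131). The largest negative terms included Hemgn (-3.12), Pklr (-3.09), the red cell membrane gene Rhag (-3.08), Gata1 (-2.81) and Epor (-2.76). Igfbp2, named after its values were seen, had an interaction of 0.65 (adjusted p = 0.0429). Smarca4 stood at 0.29 (adjusted p = 0.310) and Nkx2-5 at 0.50 (adjusted p = 0.271). The count was 625, 14, 3224 and 560 without Nkx2-5+/- replicates 1, 2, 3 and 4, and 6 and 8 without Nkx2-5+/-;Brg1+/- replicates 1 and 2. It was 495 without Brg1+/- replicate 2, and 615, 543 and 597 without wild-type replicates 1, 4 and 5. It was 0 with the erythroid list mean as a covariate (Tbx5 at 0.59, Apela at 1.19, Hemgn at 0.062), 25 with the arrays of these groups alone, 2288 with the principal component, 3258 without the pair of arrays whose Smarca4 went against the label and 4235 with array weights.

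By group, the erythroid list carried the largest interaction, with a median of -2.33, 12 of 15 genes negative over all genes and 15 adjusted over the list alone (camera adjusted p = 5.0e-15; adjusted p = 0.206 with an estimated correlation). Beside it, 5 of 13 epicardial genes had a positive term, 12 adjusted over the list alone (median 0.78, camera adjusted p = 1.3e-09; adjusted p = 0.179 with an estimated correlation), among them the transcription factor genes Tcf21 (0.84) and Bnc1 (1.004) and the mesothelial gene Upk3b (0.79). Of 32 sarcomere genes 4 passed, 17 adjusted over the list alone, all positive (median 0.67, camera adjusted p = 2.5e-09; adjusted p = 0.252 with an estimated correlation), including Csrp3 (0.82), Tnni3 (0.78) and Smpx (0.76). Of 27 cell cycle genes 5 were negative, 11 adjusted over the list alone (median -0.41, camera adjusted p = 5.1e-09; adjusted p = 0.206 with an estimated correlation), with Kif11 at -0.99 and Aurka at -0.67. The atrial factors Nr2f1 (1.07) and Nr2f2 (0.86) were among 3 of 17 chamber genes (median 0.56, 10 adjusted over the list alone, camera adjusted p = 1.7e-06; adjusted p = 0.206 with an estimated correlation). Bmp4 (0.97) was among 3 of 20 Bmp and Tgf-beta genes (median 0.53, 11 adjusted over the list alone, camera adjusted p = 2.1e-05; adjusted p = 0.206 with an estimated correlation). Gata6 (0.81) and Hand2 (0.64), regulators of heart formation, were among 6 of 40 cardiac transcription factors, with 7 positive and 1 negative adjusted over the list alone (median 0.40, camera adjusted p = 6.9e-05; adjusted p = 0.252 with an estimated correlation). The cushion mesenchyme list stood at 0.63 with 2 of 18 positive, 10 adjusted over the list alone (camera adjusted p = 1.7e-06; adjusted p = 0.206 with an estimated correlation). Cox7a1 (0.92) and Cox6a2 (0.89) passed among 19 mitochondrial genes, 8 adjusted over the list alone (camera adjusted p = 1.6e-04; adjusted p = 0.320 with an estimated correlation). The macrophage genes Csf1r (0.95) and Mrc1 (0.996) passed among 16 leukocyte genes, 5 adjusted over the list alone (camera adjusted p = 0.0044; adjusted p = 0.389 with an estimated correlation). Single genes of other groups included Erbb2 (0.69), Dusp1 (-1.21) and the BAF subunit gene Pbrm1 (-0.56). The leukocyte call ended without Nkx2-5+/- replicate 3 (camera adjusted p = 0.311). In all 18 lists were called, of which 6 held with the erythroid list mean as a covariate.

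The single losses were also compared with each other across genes, which are not independent replicates. The log2 fold changes of the Brg1+/- and Nkx2-5+/- arrays against the shared wild-type arrays had a correlation of 0.765 and a covariance of 0.0319. Simulated unchanged groups gave medians of 0.449 (range -0.0439 to 0.814) and 0.0079 (highest 0.0216). These groups and a control set that they shared were drawn at random from the residuals of all 27 arrays, not from the wild-type arrays alone. The Brg1+/- and Nkx2-5+/- arrays both had a raised erythroid median, 0.88 and 1.26. With the wild-type arrays split between the comparisons in 20 ways, the median correlation was 0.491 (range 0.288 to 0.615) and the median covariance 0.0241. These comparisons shared 1 gene that fell, Igfbp2, where independent lists would share 0.103, and they shared 0 by limma in each of 20 ways of splitting the wild-type arrays. The Brg1+/- and Tbx5+/- arrays gave a correlation of 0.179 and a covariance of 0.0037 (simulated medians 0.467 and 0.0079). The observed correlation lay inside the simulated range of -0.179 to 0.787. With the wild-type arrays split, the median correlation of these arrays was -0.0545 (range -0.463 to 0.132). The Tbx5+/- and Nkx2-5+/- arrays gave 0.0380 and 0.0012 (simulated medians 0.460 and 0.0083). The simulated correlations ran from -0.0040 to 0.703, and the median with the split was -0.0960 (range -0.448 to 0.153). The compound groups gave 0.261 and 0.0068 (simulated medians 0.333 and 0.0082). Here the simulated correlations ran from -0.376 to 0.712, and the median with the split was -0.00984 (range -0.274 to 0.252). The observed correlations of these last 2 pairs thus lay inside the simulated ranges.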

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

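The tests of array medians, of a swap of arrays and, in its final form, of blood in the interaction were chosen after the results were seen, as was the fit without the pair of arrays. The prediction for the interaction as first written, before the result, named the slope alone and overlooked the negative sign of the erythroid term.

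The effect of Brg1 loss differed between hearts with and without the Nkx2-5 deletion in 987 genes by the interaction test. Named genes with a positive interaction were Tbx5 (0.88), Lum (1.42), Shox2 (1.31), Fbln2 (1.15), Myoz2 (1.23), Apela (1.12), Spon2 (1.23), Gata6 (0.81), Hand2 (0.64), Csrp3 (0.82), Tnni3 (0.78), Smpx (0.76), Nr2f1 (1.07), Nr2f2 (0.86), Bmp4 (0.97), Tcf21 (0.84), Bnc1 (1.004), Upk3b (0.79), Erbb2 (0.69), Cox7a1 (0.92), Cox6a2 (0.89), Csf1r (0.95), Mrc1 (0.996) and Igfbp2 (0.65). Those with a negative interaction were Hemgn (-3.12), Pklr (-3.09), Rhag (-3.08), Gata1 (-2.81), Epor (-2.76), Aurka (-0.67), Kif11 (-0.99), Dusp1 (-1.21) and Pbrm1 (-0.56). Other splits of the arrays gave as many genes in 2 of 100, the real one included, with 1600 as the highest other count. The split with that higher count had an erythroid term of 2.33, against -2.17 for the real one. A chance imbalance of the erythroid signal between groups is therefore not excluded as the source of the count.

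A difference in blood content between groups may account for part or most of the 1572 genes of the Nkx2-5+/- comparison and the 987 genes of the interaction. With the erythroid list mean as a covariate, 4 and 0 genes were called. This covariate cannot tell blood content from an effect of the deletion that goes with it. Slopes on the erythroid mean, estimated within arrays outside the comparison, predicted the changes of 1568 called genes with r = 0.876 across genes and the same sign for 88.6% of them, where the erythroid mean differed by 1.18, and the changes of 975 genes of the interaction with r = 0.899 and the same sign for 93.7%. Over all genes r was 0.563 and 0.599, and the observed changes were 0.888 and 0.616 times the predicted ones, against 1.82 and 1.34 times over the called genes, which were selected for large changes. Array-wide shifts left by the normalization are argued against, since 1173 of the 1572 genes were called with array medians equalised. An effect of the Nkx2-5 deletion on heart muscle or on blood itself remains open and untested.

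The pair of arrays with Smarca4 against the label may carry other genotypes than labelled. The Nkx2-5 signal of Nkx2-5+/- replicate 3, 9.40, goes with a swap of these arrays with each other, since it lies above the 8.48 to 9.24 of the other arrays labelled with an Nkx2-5 deletion. The erythroid mean of this array was also lower than in the others of its group (9.96 against 11.77 to 11.91). Whether that bears on its Nkx2-5 signal was not tested. A swap is argued against by the Lyz2 signal of Nkx2-5+/- replicate 3, 6.17. This lies inside the 5.60 to 6.44 of the other arrays labelled with an Nkx2-5 deletion and below the 6.99 to 8.21 of the arrays without. It is argued against also by Tbx5+/-;Brg1+/- replicate 3, whose Lyz2 (7.86) and Nkx2-5 (9.65) lie in the ranges without the deletion (Nkx2-5 8.99 to 10.01). Lyz2 was picked after its low values were seen in these same arrays, Nkx2-5+/- replicate 3 included. It lies on another chromosome than Nkx2-5, so it does not read the Nkx2-5 genotype directly. Whether Nkx2-5+/- replicate 3 carries a Brg1 deletion, or Tbx5+/-;Brg1+/- replicate 3 lacks it, cannot be told apart from correct labels by the score over 13 genes (0.197 and 0.363), because the ranges of the groups with and without the deletion overlap. They were 0.229 to 0.542 in the other Nkx2-5+/- and 0.273 to 0.389 in the Nkx2-5+/-;Brg1+/- arrays, both above 0.197, and 0.137 to 0.355 in the Tbx5+/- and 0.158 to 0.284 in the other Tbx5+/-;Brg1+/- arrays, both below 0.363, and no biological explanation was tested. The 13 genes were picked between Brg1+/- and wild type at an unadjusted limma p under 0.001, a number that chance alone could give. Arrays labelled Tbx5+/- also scored above every wild-type array (highest 0.131), so the score could not decide the question.

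Single arrays lay far from the others of their group in 25 of 392 groups of values, where chance gives 19.6. Nkx2-5+/- replicate 3 gave 9 of these: high for Nkx2-5 (9.40, others 8.48 to 8.63), Irx4 (8.60, others 7.02 to 7.28), Lrrc10 (7.27, others 6.11 to 6.24), Hand2 (8.18, others 7.59 to 7.66) and Csrp3 (11.67, others 10.62 to 10.79), and low for Sptb (9.32, others 11.33 to 11.74), Mki67 (10.61, others 11.95 to 12.22), Btg2 (7.25, others 8.28 to 8.44) and the erythroid mean (9.96, others 11.77 to 11.91). Tbx5+/- replicate 3 gave 7: low for Tbx5 (8.51, others 8.80 to 8.90) and Kcna5 (5.64, others 5.92 to 6.02), and high for Gja5 (9.74, others 8.95 to 9.09), Tcf21 (9.70, others 9.36 to 9.42), Slc17a7 (6.58, others 6.10 to 6.22), Tbx18 (9.75, others 9.13 to 9.28) and Aebp1 (8.75, others 8.07 to 8.22). Wild-type replicate 6 was high for Tbx5 (8.96, others 8.40 to 8.56) and Shox2 (7.68, others 6.68 to 6.93), replicate 1 for Smarcd3 (9.23, others 8.97 to 9.01) and replicate 2 for Btg2 (7.65, others 7.21 to 7.34). Brg1+/- replicate 1 was low for Sema3c (6.98, others 7.53 to 7.79), replicate 2 low for Cox7a1 (9.46, others 9.85 to 9.99) and replicate 5 high for Cd82 (9.82, others 9.17 to 9.34). Tbx5+/- replicate 2 was high for Gimap9 (6.48, others 6.24 to 6.28) and replicate 1 for Des (10.80, others 10.63 to 10.66).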

How the results depend on the processing

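The fits without the pair of arrays whose Smarca4 went against the label, and all pooled comparisons, were added after the data were seen. Of the 163 values of named genes, all 163 kept their direction and their side of the threshold with the mean of a gene's probe sets and 160 with the first residual principal component as a covariate, where 3 more were called. All 159 that remained did so without the third of genes with the lowest means. The number that kept both was 148 with the Y-linked mean as a covariate, 141 with all probe sets, 151 with array medians equalised, 147 with array weights, 153 after a further quantile normalization, 152 with a trended robust variance prior, 156 without the pair of arrays, 64 with the erythroid list mean as a covariate and 61 with the arrays of the compared groups alone. The last setting leaves fewer arrays to estimate the spread, and the other causes were not tested. Probe sets with a signal near background limit small changes, and 8194 probe sets had a mean below log2 5.

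Counts that moved by over 1.5 times are grouped by setting. With the arrays of the compared groups alone, 1 gene was called in Brg1+/- against wild type, 4 in Nkx2-5+/-, 1 in Tbx5+/-;Brg1+/-, 0 in Nkx2-5+/-;Brg1+/-, 0 between Nkx2-5+/-;Brg1+/- and Nkx2-5+/-, and 25 in the Nkx2-5 by Brg1 interaction. With array weights the counts were 3744 in Nkx2-5+/-, 6 in Tbx5+/-;Brg1+/- and 1156 in Nkx2-5+/-;Brg1+/- against wild type. They were 2 between Tbx5+/-;Brg1+/- and Tbx5+/-, 3680 between Nkx2-5+/-;Brg1+/- and Nkx2-5+/-, 2 in the Tbx5 by Brg1 interaction and 4235 in the Nkx2-5 by Brg1 interaction. With the erythroid list mean as a covariate they were 1 in Brg1+/- and 4 in Nkx2-5+/- against wild type, 1 between Nkx2-5+/-;Brg1+/- and Nkx2-5+/-, 1 in the Tbx5 by Brg1 interaction and 0 in the Nkx2-5 by Brg1 interaction. With the first residual principal component they were 2992 in Nkx2-5+/-, 1 in Tbx5+/-;Brg1+/- and 14 in Nkx2-5+/-;Brg1+/- against wild type. They were 1206 between Nkx2-5+/-;Brg1+/- and Nkx2-5+/-, and 2288 in the Nkx2-5 by Brg1 interaction. Without the pair of arrays they were 4 in Brg1+/-, 4346 in Nkx2-5+/- and 11 in Nkx2-5+/-;Brg1+/- against wild type, as well as 2363 between Nkx2-5+/-;Brg1+/- and Nkx2-5+/-, and 3258 in the Nkx2-5 by Brg1 interaction. All probe sets gave 4 in Brg1+/-, 1 in Tbx5+/-;Brg1+/- and 1 in Nkx2-5+/-;Brg1+/- against wild type. The Y-linked mean as a covariate gave 1 in Brg1+/- and 1 in Nkx2-5+/-;Brg1+/- against wild type, and 3 between Nkx2-5+/-;Brg1+/- and Nkx2-5+/-. A further quantile normalization gave 1 in Brg1+/- and 3 in Nkx2-5+/-;Brg1+/- against wild type, where 0 rose and 3 fell against 2 and 5 before. Between Nkx2-5+/-;Brg1+/- and Nkx2-5+/- it gave 136, of which 76 rose and 60 fell against 7 and 1 before, while equalised medians gave 1, a trended robust prior 88 and the removal of low genes 140. With equalised medians 1 rose and 5 fell in Nkx2-5+/-;Brg1+/- against wild type, and the interaction of Nkx2-5 with Brg1 had 284 positive and 517 negative terms, against 445 and 542 before. The removal of low genes gave 685 positive terms there. In Nkx2-5+/-;Brg1+/- against wild type, 1 rose and 5 fell without the low genes, and 0 rose and 5 fell with a trended robust prior. Between Nkx2-5+/-;Brg1+/- and Nkx2-5+/-, 8 rose and 0 fell with all probe sets.

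Of the 94 gene list calls, 0 held with an estimated correlation, which gave 0 calls. The directional test fry gave 23 calls, and the erythroid list mean as a covariate gave 47, of which 41 were among the 94. Pooled over backgrounds, the Brg1 deletion gave 7 genes without the pair of arrays and 5 with the erythroid list mean as well, the Tbx5 deletion 1 with both changes, and the Nkx2-5 deletion 26 with the erythroid list mean, 1238 without the pair and 1295 with both. With the wild-type arrays split in 20 ways, the median correlation of Brg1+/- with Nkx2-5+/- changes was 0.491 (range 0.288 to 0.615). The medians were -0.0545 for Brg1+/- with Tbx5+/-, -0.0960 for Tbx5+/- with Nkx2-5+/- and -0.00984 for the compound groups. Single splits of these pairs lay on both sides of 0 (-0.463 to 0.132, -0.448 to 0.153 and -0.274 to 0.252), so no change of sign is shown.

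Leaving out each array in turn gave 1 to 3 genes in Brg1+/-, 0 in Tbx5+/-, 66 to 4368 in Nkx2-5+/-, 0 in Tbx5+/-;Brg1+/- and 0 to 8 in Nkx2-5+/-;Brg1+/- against wild type. It gave 0 between Tbx5+/-;Brg1+/- and Tbx5+/-, 0 to 2308 between Nkx2-5+/-;Brg1+/- and Nkx2-5+/-, 0 in the Tbx5 by Brg1 interaction and 6 to 3224 in the Nkx2-5 by Brg1 interaction. Gene list calls ranged from 81 to 101, and the pooled deletions gave 1 to 2 for Brg1, 1 to 2 for Tbx5 and 5 to 1220 for Nkx2-5. Signs turned in the liver list of Brg1+/- by its test direction (medians -0.435 to -0.0506), Smarca4 in Tbx5+/- (-0.031 to 0.046), Tbx5 in Nkx2-5+/-;Brg1+/- (-0.093 to 0.019) and Nkx2-5 between Tbx5+/-;Brg1+/- and Tbx5+/- (-0.13 to 0.025).

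Directions reversed with the erythroid list mean as a covariate for lists by their test direction, where the value given is the median. These were sarcomere (0.026), chamber myocardium (0.041), Notch (-0.015) and erythroid (0.031) in Brg1+/-. In Nkx2-5+/- they were endothelium (-0.00894), Notch (0.030) and erythroid (0.00725). In the interactions they were erythroid (0.012) for Tbx5 by Brg1, and endothelium (0.015) and erythroid (0.0049) for Nkx2-5 by Brg1. The erythroid list is the covariate itself, so its change is removed by construction. Nkx2-5 reversed to 0.028 in Brg1+/-, -0.048 between Nkx2-5+/-;Brg1+/- and Nkx2-5+/-, -0.047 in the Tbx5 by Brg1 interaction and -0.076 in the Nkx2-5 by Brg1 interaction. Smarca4 reversed to -2.81e-04 in Tbx5+/- and Hemgn to 0.062 in the Nkx2-5 by Brg1 interaction. A further quantile normalization reversed Smarca4 in Tbx5+/- (-0.010) and Tbx5 in Nkx2-5+/-;Brg1+/- (0.0079). Without the pair of arrays, Nkx2-5 between Tbx5+/-;Brg1+/- and Tbx5+/- was 0.025. The causes were not tested.

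The labels give replicate numbers that are not said to mark litters or batches. Deviations of the 55 same-numbered pairs of arrays had correlations from -0.453 to 0.405 with a median of 0.012, 18 were over 0.1, as were 52 of 244 pairs with other numbers, and the best match was the own number in 22 of 55. Since not every same-numbered pair was over 0.1, the numbers were not taken as pairs. This rule is strict, and the number of best matches that chance gives was not computed. The values therefore do not exclude that some numbers mark litters or batches. With the replicate number as a block, 1 gene was called in Brg1+/-, 1 in Tbx5+/-;Brg1+/- and 3 in Nkx2-5+/-;Brg1+/- against wild type and 412 between Nkx2-5+/-;Brg1+/- and Nkx2-5+/-, and the other totals stayed within 1.5 times. In Nkx2-5+/- against wild type 262 rose and 858 fell under the block, against 543 and 1029 before. Of the 163 named values, 147 kept their direction and their side of the threshold under the block, 15 were no longer called and 1 was newly called. Of the 94 gene list calls 81 held under it, with 1 of 8 in Tbx5+/-;Brg1+/- against wild type, and it called 89 in all. Of the 412 genes between Nkx2-5+/-;Brg1+/- and Nkx2-5+/-, 134 rose and 278 fell.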

Other observations

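All pooled comparisons, and with them their splits, and the tests of Lyz2 were chosen after the results were seen. The splits of the arrays for the other comparisons were planned before. Each deletion was averaged over the groups that carry it against the groups that differ from them by that deletion alone. Pooled in this way, the Nkx2-5 deletion came with 16 genes past the limma test, 12 lower and 4 higher. Lyz2 fell by 1.54 (SE 0.15, adjusted p = 6.5e-07), Lyz1 by 1.17 (adjusted p = 5.2e-06), Igfbpl1 by 0.90 (adjusted p = 4.8e-04) and the heart muscle gene Lrrc10 by 0.89 (adjusted p = 0.0035). The slow troponin gene Tnnt1 fell by 0.79, Fam189a2 by 0.81 and Tagln3 by 0.71. Also lower were the vessel growth factor gene Angpt1 (-0.68), the heart development factor Hopx (-0.64), the lipoprotein receptor gene Vldlr (-0.60), the cholinesterase gene Bche (-0.58) and Tspyl4 (-0.40). The fast troponin gene Tnnt3 rose by 0.74, the protamine gene Prm1 by 0.58, the cyclase gene Adcy1 by 0.50 and the serotonin synthesis gene Tph2 by 0.29. All 16 stayed called with the erythroid list mean as a covariate, without the pair of arrays whose Smarca4 went against the label, and with both changes. Nkx2-5 itself stood at -0.60 (adjusted p = 0.0561), and at -0.58 (adjusted p = 0.0119) with the covariate and -0.71 (adjusted p = 0.0010) without the pair. Left-out arrays that moved the count by over 1.5 times were Brg1+/- replicates 1 (8), 2 (33), 3 (5), 4 (6) and 5 (9), Nkx2-5+/- replicates 2 (5), 3 (1220) and 4 (7), Nkx2-5+/-;Brg1+/- replicate 2 (5), and wild-type replicates 1 (5), 2 (9), 4 (8), 5 (9) and 6 (26).

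Pooled over backgrounds, the Tbx5 deletion came with a fall of Gja5 by 0.80 (SE 0.13, adjusted p = 0.0105) and a rise of Ddc, the decarboxylase of dopamine and serotonin synthesis, by 0.86 (SE 0.12, adjusted p = 0.0027). The Gja5 call ended without Tbx5+/-;Brg1+/- replicate 3, which left 1 gene, and with both changes together Gja5 was at -0.79 (adjusted p = 0.0437) and Ddc at 0.82 (adjusted p = 0.0682). Kcna5 stood at -0.49 (adjusted p = 0.340) and Tbx5 at 0.36 (adjusted p = 0.356). The pooled Brg1 deletion came with 1 gene, Smarca4, which fell by 0.52 (adjusted p = 3.1e-04). Igfbp2 stood at -0.37 (adjusted p = 0.392) and Nppb, a natriuretic peptide gene of the ventricles, at 0.46 (adjusted p = 0.923). Without the pair of arrays 7 genes passed, among them Igfbp2 (-0.43, adjusted p = 0.0479) and Nppb (0.60, adjusted p = 0.0192). The count was 2 without Nkx2-5+/-;Brg1+/- replicate 3.

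Lyz2 and Lyz1 were low in every array labelled with an Nkx2-5 deletion, and a chromosome segment around Lyz2 that the labelled hearts share may be the source. Fewer leukocytes are argued against as the source of the whole fall, because the other 15 leukocyte and platelet genes had a median pooled change of -0.0524. The 95% bootstrap interval, over genes and not hearts, was -0.110 to -0.00692, far above the -0.770 that is the change of Lyz2 divided by 2. The pooled change subtracts the Brg1+/- arrays, whose leukocyte list was itself lower than wild type. Against wild type alone, Mrc1 (-0.70) and Csf1r (-0.58) were also called lower in Nkx2-5+/- arrays, so a smaller loss of leukocytes remains open. Of the other 15 genes called for the pooled Nkx2-5 deletion, 3 (Lyz1, Lrrc10 and Tph2) lay within 5 Mb of Lyz2 among 57 genes there (permutation p = 3.0e-05), and 2 did without Lyz1, a paralog that may share probes (permutation p = 6.4e-04). The window was placed around Lyz2 after its fall was seen in the same data. Lrrc10 did not follow Lyz2 in every array. In Nkx2-5+/- replicate 3 it was 7.27, near the wild-type mean of 7.49, while Lyz2 was low there (6.17). Tph2 rose by 0.29, while Lyz2, Lyz1 and Lrrc10 fell. The 57 neighbours had a median change of -0.034, and Lyz2 and Nkx2-5 lie on different chromosomes. Genotype of the segment was not tested, and an effect of Nkx2-5 on these genes remains open.

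Splits of the same arrays show how often a grouping gave as many genes as the real one, which is itself counted in every share below. The share was under 5 of 100 for Nkx2-5+/- against wild type, where 3 of 100 splits gave as many genes (real 1572, highest other 3360). It was so also for Nkx2-5+/-;Brg1+/- against wild type, where 1 of 84 did (real 7, highest other 3). Only in that comparison did no other split reach the real count. For the pooled deletions, chosen after the results were seen, 2 of 100 did for Tbx5 (real 2, highest other 170) and 4 of 100 for Nkx2-5 (real 16, highest other 614). Where other splits gave more genes than the real one, a small share alone does not exclude chance. The shares were not adjusted for the number of comparisons. Chance cannot be excluded either for the count in Brg1+/- against wild type, where 5 of 100 splits gave as many (real 2, highest other 799), while Smarca4 itself was called there in all 25 alternatives (highest adjusted p = 0.0026). Nor can it be excluded for Nkx2-5+/-;Brg1+/- against Nkx2-5+/-, where 6 of 35 did (real 8, highest other 3080, a split whose erythroid means differed by 1.80), or for the pooled Brg1 deletion, where 7 of 100 did (real 1, highest other 2652). A real count of 0 is matched by every split by construction, so these splits say nothing about chance. They were 100 of 100 for Tbx5+/- against wild type (highest other 1), 84 of 84 for Tbx5+/-;Brg1+/- against wild type (highest other 3), 56 of 56 for Tbx5+/-;Brg1+/- against Tbx5+/- (highest other 1) and 100 of 100 for the Tbx5 by Brg1 interaction (highest other 1). By limma these 0 counts stood beside 788, 873, 494 and 606 genes at an unadjusted p under 0.05. What set apart the splits with many more genes than the real one was not tested.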
